A study of Mus musculus with 4 samples.

How the data were processed

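Chromatin immunoprecipitation followed by sequencing (ChIP-seq) had been carried out on N2A cells, a mouse neuroblastoma line, exposed to 15 µM hemin for 12 h or to the DMSO vehicle. Per the labels' protocols, fixation was in 1% formaldehyde (10 min) and the chromatin was sonicated. For each treatment there was 1 library made with an antibody against trimethylated lysine 9 of histone H3 (H3K9me3) and 1 control library. The titles call the control an input, while its antibody label and the design text speak of IgG, so it is called the control library here. The design text speaks of triplicates, but the 4 libraries used here are 1 per group, so there were no replicates to pair across groups.

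The deposited files held aligned reads, 1 interval per line with its strand and no header. Per the submitters' processing notes, fastp 0.23.2 and MACS 1.4.2 and the build mm10 were used, with no role or order given for either tool. The aligner, the mapping filter and the treatment of duplicates were not given in the sources used here. The score column deposited by the authors held 0 in every line, so it carried no mapping quality and was not used. No read names or mate marks were in the lines. On chromosome 19, the number of minus-strand ends lying 100 to 600 bp beyond a plus-strand start exceeded the background by 1.12 per plus read in the vehicle H3K9me3 library, 1.17 in the hemin H3K9me3 library, 1.35 in the vehicle control and 1.43 in the hemin control. The modal distances were 218, 209, 294 and 294 bp. Both ends of a fragment were thus treated as being listed, and only plus-strand reads were counted, 1 per start position, by the midpoint of the interval, on chromosomes 1 to 19 and X. The counts are called fragments here. Duplicates removed in this way were 5.83% of the plus-strand reads in the vehicle H3K9me3 library, 6.85% in the hemin H3K9me3 library, 3.63% in the vehicle control and 5.51% in the hemin control.

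Fragments were counted in 10 kb windows, since H3K9me3 forms broad domains, and scaled to the total number of fragments of the library. A window was called enriched where the H3K9me3 library held at least 2 times the scaled fragments of the control library of the same treatment, with at least 10 fragments in each control. For comparing treatments, enriched windows were called on both H3K9me3 libraries summed against both controls summed, so that neither treatment selected them. The hemin over vehicle ratio was taken with a pseudocount of 1 fragment, and a difference of at least 1.5-fold was counted. This log2 ratio with the pseudocount also ranked the named genes and gave the list medians, while the ratios printed for single genes and regions, with their intervals, carry no pseudocount. Each count was set beside the same count in the control pair and beside 100 simulations of the pair with no difference. Gene regions covered both ends of each protein-coding gene ± 2.5 kb, with overlapping ends counted once. The plan had been to use the transcription start alone, but the gene table (assembly GRCm38.p6, the coordinates of mm10) carried no strand, so the start could not be told from the end. Of 21627 protein-coding genes, 20603 had at least 20 fragments over both H3K9me3 libraries and at least 10 in each control. Gene density was the number of protein-coding genes within 500 kb.

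With 1 library per group no test across replicates was possible, so no p-values are given. Shares carry exact Clopper-Pearson 95% intervals and ratios carry exact conditional binomial 95% intervals, which cover counting error only. Ratios of ratios (the control-corrected Tfrc gene body and the mitochondrial reads) carry intervals from a normal approximation on the log scale instead. A gene list was described by the percentile of its median among 10000 random lists of the same size, matched on scaled H3K9me3 fragments for the hemin over vehicle ratio and on control fragments for enrichment. Percentiles outside 2.5 to 97.5 were taken as standing apart. Members of clustered families lie side by side, and some protocadherin genes share an end region. They are not independent draws, so their percentiles are more extreme than independent genes would give. The 18 lists were fixed before the data were examined: ferroptosis, iron handling, heme response, H3K9 methylation machinery, imprinted genes, germline genes, neuroblast and neuronal markers, glial markers, microglia and immune markers, muscle and liver markers, housekeeping genes, Zfp zinc finger genes, olfactory receptors, vomeronasal receptors, clustered protocadherins, ribosomal protein genes, clustered histone genes and Hox genes.

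The genes named were set by a rule also fixed beforehand. Tfrc is always named. Among genes with at least 40 H3K9me3 fragments and an enrichment of at least 1.5 in at least 1 treatment, the 12 highest and the 12 lowest hemin over vehicle ratios are named, leaving out predicted genes and the less extreme of genes within 100 kb of each other. The 12 highest enrichments and the 3 lowest among housekeeping genes follow the same exclusions, and from each list the 2 highest and 2 lowest members may be named. Because these genes were picked for extreme values, their ratios overstate typical differences. Olfactory and vomeronasal receptor genes, Zfp genes and other families with close copies can share reads, and mapping quality was not given, so their single-gene values are uncertain.

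Calling was tested on simulated fragment counts drawn from the real regions and depths. Reads were not simulated, so the choice of strand, the removal of duplicates and the counting in regions were not tested. For gene regions in the hemin against vehicle comparison, over 20603 regions, 86% of the regions set to a 2-fold difference and 99% of those set to a 3-fold difference were recovered, and 5.96% of unchanged regions passed the 1.5-fold mark. For enriched windows, over 246215 windows, 99.9% of windows set to 3-fold were recovered in the summed libraries and 98.9% in the vehicle pair. Of unenriched windows, 0.0232% and 0.338% were called. Windows set near the 2-fold mark were not simulated, so recovery there is unknown. Few real windows reached 3-fold, 553 in vehicle and 675 in hemin. Of windows enriched at least 2-fold in vehicle, 27.5% were so in hemin, and 22.3% the other way round. A simulated list of 40 genes moved by 0.2 on the log2 scale reached percentile 99.95 of random lists, and 2% of unmoved lists fell outside the 2.5 to 97.5 range.

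Alternatives fixed beforehand kept duplicates, scaled by fragments outside enriched windows, divided by the control ratio, used a pseudocount of 5, a 2-fold difference, 50 kb windows, enrichment of 1.5-fold or 3-fold, gene ends ± 1 or ± 5 kb, minimums of 50 fragments or none, and libraries thinned to equal depth. Counting both strands, using whole genes ± 2.5 kb and centring ratios on the median of the regions compared, and the share of fragments in thinned libraries, were added after seeing the data. A filter on mapping quality, also foreseen, was not run, since no mapping quality was given. Base composition and repeats were not analysed here, as no genome sequence was used. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.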

Results

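H3K9me3, a histone mark of heterochromatin and of silenced repeats and gene families, was profiled in N2A mouse neuroblastoma cells given hemin, the iron-containing porphyrin freed when hemoglobin breaks down, or its DMSO vehicle. The title of the series names ferroptosis, an iron-dependent cell death driven by lipid peroxidation, and repression of Tfr1. Tfr1 is the product of Tfrc, the transferrin receptor that takes up iron. The vehicle H3K9me3 library held 28844626 deposited reads and 13556824 counted fragments. The hemin H3K9me3 library held 28991604 reads and 13480404 fragments. The vehicle control held 28738820 reads and 13806759 fragments, and the hemin control 36300677 reads and 17096998 fragments. With 1 library per group there was no replicate check: each comparison below is between libraries, not between conditions, and intervals are 95% intervals that cover counting error only.

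The first comparison, of each H3K9me3 library with its control, asked where the mark lay. H3K9me3 over control was high at receptor genes and in gene-poor windows and low at housekeeping and ribosomal protein genes. Vomeronasal receptor genes, which encode pheromone receptors, had a median enrichment over control of 1.429 in the vehicle and 1.395 in the hemin library, and olfactory receptor genes 1.30 and 1.19. Among the single genes named for the highest summed enrichment were the olfactory receptor gene Olfr1098 with 3.23 and the zinc finger gene Zfp640 with 3.13. The lowest of the housekeeping list were Actb, which encodes cytoplasmic actin, with 0.464, the translation factor gene Eef1a1 with 0.498 and the ribosomal protein gene Rpl13a with 0.505.

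Of the other genes at the top, Olfr1161 had a summed enrichment of 2.98, Olfr1205 2.88, Olfr1222 2.79 and Olfr1458 2.74. The vomeronasal receptor genes Vmn2r72, Vmn2r109 and Vmn1r11 had 2.82, 2.77 and 2.67. Cylc2, which encodes a protein of the sperm head, had 2.70, and Mdga2, which encodes a neuronal surface protein at synapses, had 2.67. Esp24, a gene of the exocrine gland-secreted peptide family, had 2.65. Its enrichment was 5.00 in the vehicle and 1.84 in the hemin library, with 11 and 33 control fragments. Most of these rest on few fragments: Olfr1098 on chromosome 2 (86922583 to 86923530, mm10) had 37 and 28 H3K9me3 fragments against 12 and 11 control fragments in the vehicle and hemin libraries. Zfp640 (chromosome 13, 66670274 to 66680803) had 47 and 68 against 22 and 20. Across all 20603 gene regions the median enrichment was 0.798 in the vehicle and 0.731 in the hemin library. At least 2-fold enrichment was found at 266 gene regions in the vehicle library and 288 in the hemin library, 72 of them in both.

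H3K9me3 over control was higher in gene-poor windows. In windows with 0 to 1 protein-coding genes within 500 kb the median enrichment was 1.335 in the vehicle and 1.395 in the hemin library, and it was lower in each denser bin, down to 0.830 and 0.779 in windows with 14 to 72 genes. Of the gene-poorest windows, 7.27% were enriched at least 2-fold in the summed libraries. Of 246215 windows with enough control fragments, 8726 (3.54%) were enriched at least 2-fold in the vehicle and 10752 (4.37%) in the hemin library. Of these, 2400 were enriched in both, where 381 would be shared by independent sets. The controls set against each other gave 518 windows at least 2-fold higher in hemin and 409 higher in vehicle. Windows enriched in the summed libraries numbered 5902, covering 59.02 Mb, and 22.5% of them overlapped a protein-coding gene, against 46.5% of all windows. The enrichment was weak, with a 99th percentile of 2.44 in the vehicle and 2.54 in the hemin library.

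**Figure D1:**
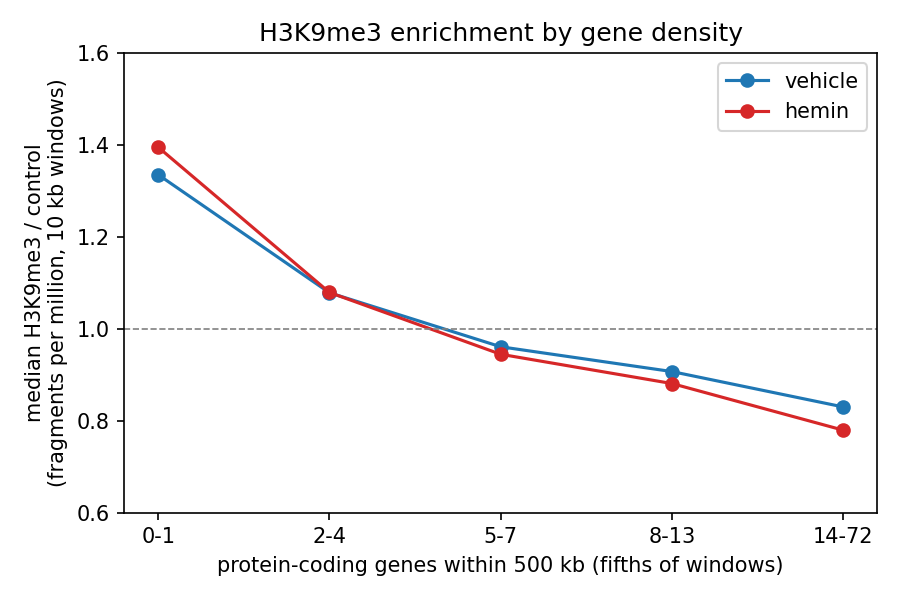
Median H3K9me3 over control ratio of 10 kb windows (y axis, scaled fragments) by the number of protein-coding genes within 500 kb (x axis), for the vehicle (blue) and hemin (red) libraries, 1 library each. The median goes from 1.335 and 1.395 in the gene-poorest windows to 0.830 and 0.779 in the densest, and the dashed line marks equal H3K9me3 and control.

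The second comparison, hemin against vehicle, asked whether the mark differed after hemin. Fragments in enriched windows made up 2.32% (2.31 to 2.33) of the hemin H3K9me3 library and 2.17% (2.16 to 2.18) of the vehicle one, a ratio of 1.07 (1.07 to 1.08). The same windows held 1.00% (0.999 to 1.01) of the hemin control and 1.01% (1.01 to 1.02) of the vehicle control, a ratio of 0.991 (0.984 to 0.998). Gene regions leaned the other way, with a median log2 ratio of −0.10 in the H3K9me3 pair and −0.005 in the control pair. Across all windows the median H3K9me3 log2 ratio went from 0.05 with 0 to 1 genes within 500 kb to −0.06 with 14 to 72. In the control pair it was −0.01 and 0.009. The leans of enriched windows and of gene regions thus need not be separate findings. Among genes with at least 40 H3K9me3 fragments and an enrichment of at least 1.5 in a treatment, the highest hemin over vehicle ratio was that of Olfr1160, at 2.60 (1.30 to 5.55). The lowest was that of Krtap14, a gene of the hair keratin-associated proteins, at 0.374 (0.181 to 0.724). Olfactory or vomeronasal receptor genes were 7 of the 12 named at the high end and 9 of the 12 at the low end. Naming required enrichment, which was highest in the receptor lists, and the receptor share of the 1292 eligible genes was not counted. The tally thus does not show that receptor genes differed more often than others.

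Among genes higher in the hemin library, Ctag2, a gene of the cancer/testis antigen family, had a ratio of 2.48 (1.33 to 4.87), but its control pair stood at 0.501. Gucy2c, which encodes the intestinal guanylate cyclase receptor, had 2.38 (1.37 to 4.31), Cldn34d, of the claudin family, 2.35 (1.38 to 4.12), and Speer4f1, of a testis-expressed family, 2.05 (1.44 to 2.95). The receptor genes Olfr1183, Vmn2r50, Olfr1281, Vmn1r75, Vmn2r24 and Olfr1209 lay between 1.91 and 2.07, as did Klhl1, which encodes a neuronal actin-binding protein, at 1.95. The interval of Olfr1209 (0.982 to 4.002) reached below 1. Among genes lower in the hemin library, Vps35, which encodes a retromer subunit for endosomal sorting, had 0.464 (0.274 to 0.767), from 52 vehicle and 24 hemin fragments, with a control ratio of 1.43. Mageb17-ps had 0.462, Olfr154 0.469, Olfr411 0.479, Olfr1286 0.484 and Olfr457 0.485. Vmn1r12, Vmn2r28, Olfr591, Olfr476 and Olfr1443 lay between 0.513 and 0.533.

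Of the 5902 enriched windows, 387 were at least 1.5-fold higher and 165 at least 1.5-fold lower in the hemin library. Simulated pairs with no difference gave means of 161 (126 to 201 over 100 simulations) and 164 (131 to 200). The control pair gave 352 higher and 465 lower, with simulated means of 443 (394 to 478) and 465 (420 to 499). The 352 thus lay below its simulated range. Real windows had to hold at least 10 fragments in each control, but the simulated pairs were not held to this. The shortfall can therefore not be read as a property of the control libraries. Of the gene regions, 429 were higher and 1445 lower. Simulated pairs gave 637 (578 to 700) and 634 (591 to 709), and the control pair gave 357 and 344. Gene regions were not chosen for enrichment, and their median enrichment was 0.798 in the vehicle and 0.731 in the hemin library. When ratios were centred on the median of the same regions, the split became 247 higher and 238 lower for windows, and 778 higher and 828 lower for gene regions. Centring brings the directions near balance by construction, so this split does not bear on whether either lean was real.

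**Figure D2:**
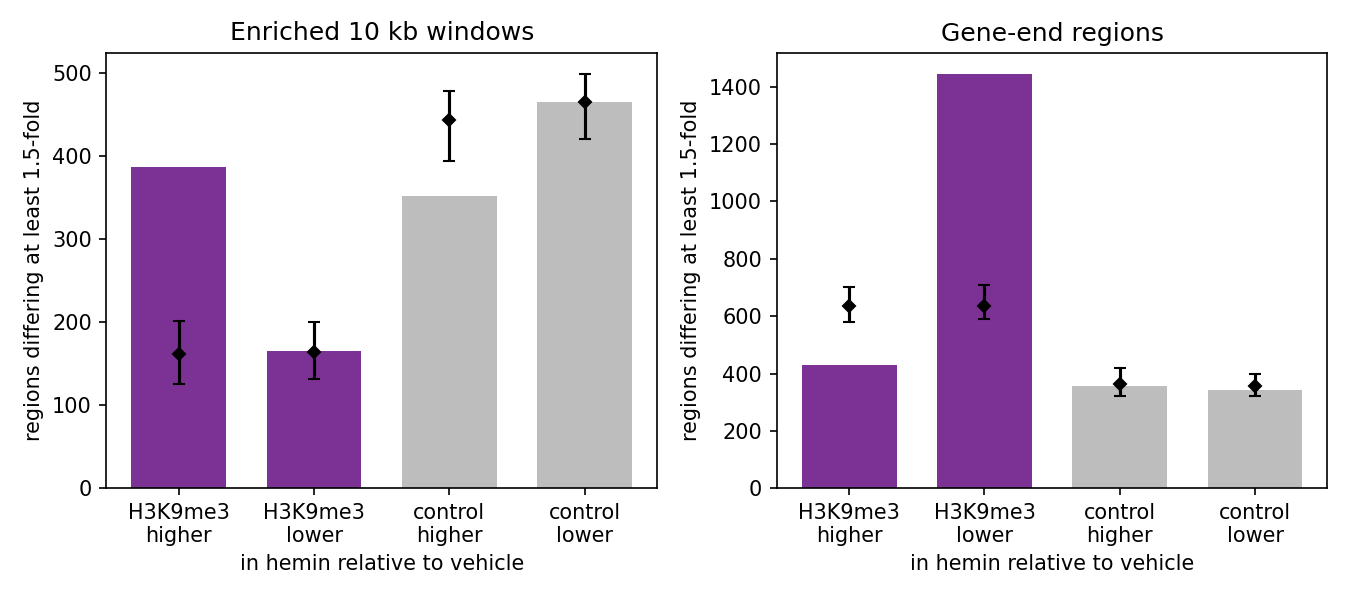
Number of regions at least 1.5-fold higher or lower in the hemin library (bars, y axis), for enriched 10 kb windows (left) and gene-end regions (right), in the H3K9me3 pair (purple) and the control pair (grey). Diamonds are means and whiskers the lowest and highest of 100 simulated pairs with no difference. In the H3K9me3 pair, 387 windows were higher against a simulated mean of 161, and 1445 gene regions were lower against 634.

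The third comparison concerned Tfrc (chromosome 16, 32608896 to 32632794, mm10), the gene named in the series title. Its gene ends carried no detectable excess of H3K9me3 at this depth, with an enrichment of 0.724 (0.510 to 1.02) in the vehicle and 0.929 (0.660 to 1.30) in the hemin library. The hemin over vehicle ratio at the ends was 1.07 (0.741 to 1.56), from 59 and 63 fragments, at percentile 73.9 of all gene regions. Over the gene body the ratio was 0.799 (0.637 to 1.00), from 180 and 143 fragments. The gene body enrichment was 1.11 (0.894 to 1.38) in the vehicle and 0.756 (0.610 to 0.933) in the hemin library, while the control pair had a ratio of 1.17 (0.959 to 1.44).

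The gene table gave no strand, so the ends of Tfrc were also read apart. The end at the lower coordinate had 19 vehicle and 27 hemin fragments and a ratio of 1.43 (0.766 to 2.72), and the end at the higher coordinate had 40 and 36 and a ratio of 0.905 (0.561 to 1.46). Over the 100 kb around the gene the ratio was 0.901 (0.797 to 1.02), with an enrichment of 0.838 (0.748 to 0.939) in the vehicle and 0.689 (0.617 to 0.769) in the hemin library. The sign at the ends depended on the region counted: the log2 ratio was 0.10 at ± 2.5 kb, −0.06 at ± 5 kb, −0.29 over the whole gene ± 2.5 kb and −0.55 at ± 1 kb. The last rested on few fragments, 7 and 7 at the lower end and 17 and 9 at the higher end.

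**Figure D3:**
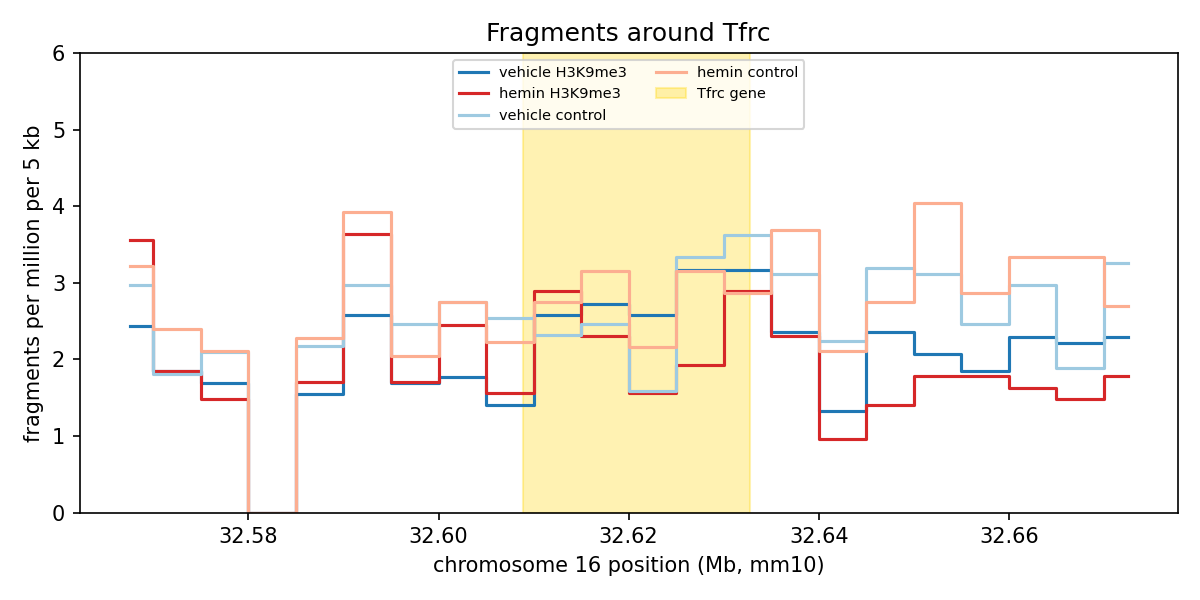
Depth-scaled fragments in 5 kb bins (y axis) along chromosome 16 around Tfrc (x axis, Mb, mm10; yellow band, the gene), for the 4 libraries, 1 per group. The H3K9me3 libraries lie above their controls in some bins and below in others, and over the whole gene body the enrichment was 1.11 in the vehicle and 0.756 in the hemin library.

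The lists were then compared as groups with random lists matched on fragment number. Ferroptosis genes, 41 in all, stood within the random range for the hemin over vehicle ratio (percentile 88.2) and for enrichment (19.8, median 0.700). Ptgs2, which encodes a prostaglandin synthase, was 1.65 (1.12 to 2.45) and the only member at least 1.5-fold higher; 3 were lower, among them Lpcat3, which encodes a phospholipid-remodelling acyltransferase, at 0.572 (0.361 to 0.892) and Nfe2l2, which encodes an antioxidant transcription factor, at 0.640 (0.407 to 0.995). The 33 iron handling genes were also within range, at percentiles 77.6 and 80.9, with 1 member higher and 3 lower. Heph, which encodes a ferroxidase, had 1.58 (0.962 to 2.64), and Hfe, the gene of the hereditary hemochromatosis protein, 0.562 (0.303 to 1.01). Of the 36 heme response genes none reached a 1.5-fold difference with the pseudocount of 1 fragment, although Ppox, of heme synthesis, stood at 0.665 (0.432 to 1.01) without it. Their ratio was at percentile 93.9, with an enrichment percentile of 2.79. The ratio lay outside the random range with duplicates kept (97.63), and the enrichment lay below it with ends ± 5 kb (0.32), both strands (0.87) and whole genes (1.31). The 34 H3K9 machinery genes had no member higher and 5 lower, including the methyltransferase gene Suv39h1 at 0.559 (0.328 to 0.931) and Uhrf1, which encodes a chromatin adaptor, at 0.570 (0.363 to 0.882). That list was at percentile 16.2, and its control pair stood apart, at 0.55. Enrichment in vehicle and hemin was 0.865 and 0.495 at Suv39h1, 0.617 and 0.385 at Uhrf1, and 0.573 and 0.399 at Lpcat3. It was 0.747 and 0.548 at Nfe2l2 and 0.711 and 1.05 at Ptgs2. At these genes the ratios thus compare regions without a detectable excess of H3K9me3.

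Enrichment percentiles were high for imprinted genes (100, median 1.16 over 26 genes), led by Nnat at 2.41, and for germline genes (99.6, median 0.879 over 43), led by Mei4 at 2.15 and Dazl at 1.69. They were also high for Zfp genes (100, median 0.882 over 360), for which Zfp981 had 2.48, and for protocadherins (100, median 0.972 over 57), so both lists stood above matched genes with a median below control. Percentiles were 100 for the 973 olfactory and 247 vomeronasal receptor genes. They were 0 for housekeeping genes (median 0.602 over 41), ribosomal protein genes (0.593 over 79) and clustered histone genes (0.661 over 67). The histone percentile rested on the matching: among lists matched on gene density it was 7.17. Neuroblast and neuronal, glial, microglia and immune, muscle and liver and Hox lists were within range, at percentiles 71.4, 80.1, 69.3, 84.0 and 48.5.

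For the hemin over vehicle ratio, Zfp genes (percentile 100, 17 higher and 24 lower), olfactory receptor genes (100, 42 higher and 72 lower) and vomeronasal receptor genes (100, 11 higher and 15 lower) had medians above those of matched lists. The medians were −0.02, −0.04 and 0.01 on the log2 scale, where matched lists had −0.09, −0.11 and −0.11. Matching was on H3K9me3 fragments, not on enrichment. These percentiles thus do not separate the families from the larger hemin share in enriched windows as a whole. Control pairs stood apart as well for imprinted genes (percentile 98.5), olfactory receptor genes (99.5) and protocadherins (100). The protocadherin ratio was at 94.8, with 6 members higher and 5 lower, such as Pcdhga12 at 1.86 (1.14 to 3.09) and Pcdhb14 at 0.536 (0.313 to 0.899). Pcdhga12, Pcdhgb2 and Pcdhgc3 share 1 end, whose 19 vehicle and 31 hemin H3K9me3 fragments enter each of them. The member counts and percentiles of this list, in the control pair too, thus count some fragments repeatedly. Imprinted, germline, neuronal, glial, immune, muscle and liver, housekeeping, ribosomal protein, histone and Hox lists had ratio percentiles of 79.0, 83.0, 4.95, 72.8, 35.7, 77.6, 8.12, 27.3, 17.9 and 92.9, all within the random range. At ± 1 kb the Zfp and vomeronasal lists lay inside it, at 58.8 and 93.4, and dividing by the control ratio put the olfactory list at 90.2. The protocadherin list lay above the range with duplicates kept (99.98), ends ± 5 kb (99.96), both strands (99.94) and whole genes (100), and the housekeeping list below it with whole genes (0.14).

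**Figure D4:**
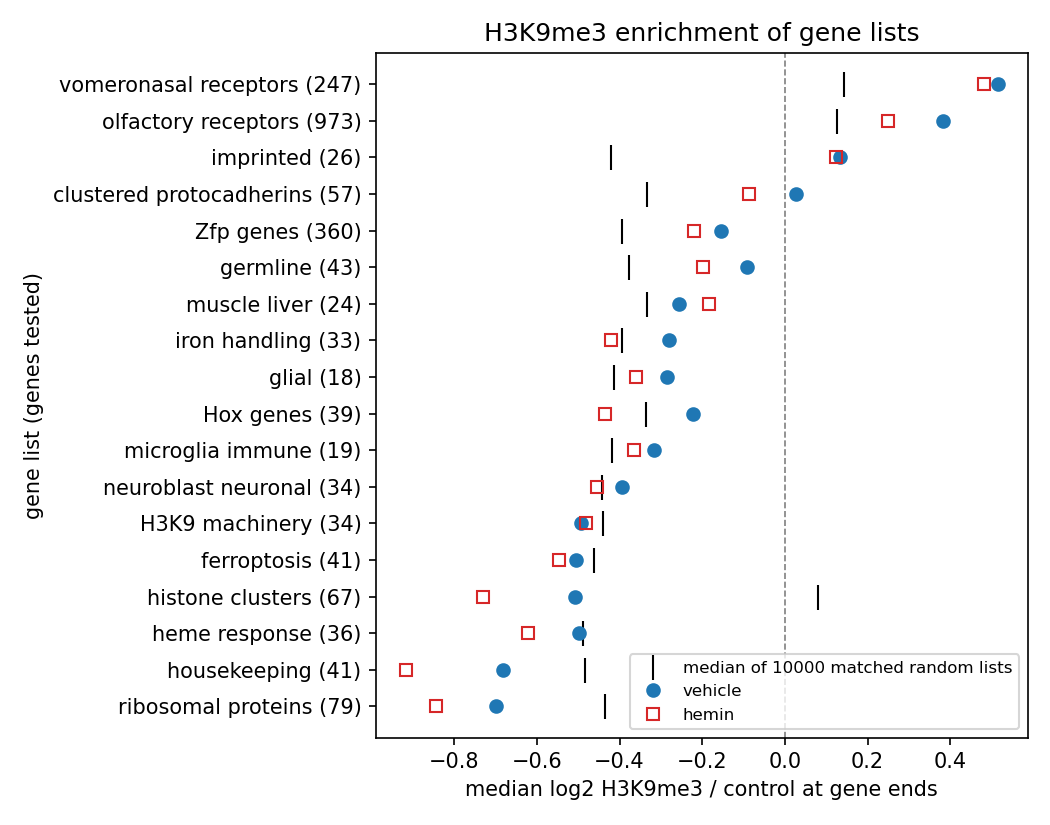
Median log2 H3K9me3 over control at gene ends (x axis) for each gene list (y axis, number of genes tested in parentheses), in the vehicle (blue circles) and hemin (red squares) libraries. Black ticks are the medians of 10000 random lists matched on control fragments. Receptor lists lie to the right of their ticks, and housekeeping, ribosomal protein and histone lists to the left.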

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

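The tests of the share in thinned libraries, of mitochondrial reads, of hemin treatment, of differences between control libraries and of base composition were chosen after the results they bear on were seen, and so was the use of a counting interval in reading the test of a loss at Tfrc.

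Enriched windows held a larger share of the hemin than of the vehicle H3K9me3 library, and more windows were enriched. A deeper hemin control did not account for either. With all libraries thinned to 13480404 fragments, the share ratio was 1.07 (1.07 to 1.08), and the ratio of hemin-enriched to vehicle-enriched windows was 1.29. Windows enriched in hemin alone outnumbered those in vehicle alone by 1.41 (1.36 to 1.45). That interval counts windows, not fragments, as independent draws. Windows of a treatment share the same libraries, so it can be too narrow. Duplicate reads did not account for the share, since its ratio of 1.07 (1.065 to 1.076) was measured with them removed; it was 1.074 with them kept. Mitochondrial reads, which come from DNA without histones, were lower over control in the hemin than in the vehicle H3K9me3 library by a ratio of ratios of 0.423 (0.402 to 0.445), consistent with less unspecific background in the hemin immunoprecipitation. Hemin treatment itself, with a share ratio of 1.07, cannot be told apart from the library, because each treatment had 1.

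H3K9me3 over control was higher in gene-poor windows, and Zfp genes stood above matched genes. A bias that follows gene density did not account for the Zfp genes, which were at percentile 100 of lists matched on gene density. A difference between control libraries did not account for the windows enriched in both treatments, which were 6.30 times as many as independent sets would share. For windows enriched in 1 treatment alone it was not the whole cause: when windows were picked on a random part of the H3K9me3 fragments, the remaining fragments over the control of the other treatment gave 1.44 (1.435 to 1.452) in vehicle and 1.598 (1.590 to 1.606) in hemin, against 1.88 and 1.94 over their own control and a median of 1.01 for all windows. Base composition remains open: the median vehicle enrichment in the gene-poorest windows was 1.335, and without a genome sequence windows could not be matched on it; no biological explanation was tested.

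Over the Tfrc gene body, vehicle enrichment was above 1 and hemin enrichment below it, with a ratio of enrichments of 0.680. The difference was not tested across replicates, of which there were none. Its approximate counting interval on the log2 scale, −0.98 to −0.12, excluded 0. However, 4277 genes with similar counts had a median of −0.116, not 0, and the upper limit of −0.1245 lay only just below that. Ordinary scatter between libraries may account for the difference. The control-corrected log2 ratio of −0.55 was at percentile 3.34 of these genes, inside their central 95% (−0.59 to 0.40). A loss specific to Tfrc had been set, beforehand, to be excluded by any percentile inside the central 95% of such genes, which both 3.34 and the uncorrected 16.4 meet. That reading was softened after these percentiles were seen: that counting interval, and the exact uncorrected one of −0.65 to 0.001, which includes 0, reach past the lower limits of −0.59 and −0.53, so a loss at Tfrc is neither shown nor excluded at this depth. Without that later step it would count as excluded.

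Reads outside the main chromosomes stood above control in 3 cases. Like the mitochondrial reads, they are plus-strand reads with duplicates kept, which their intervals treat as separate reads. Chromosome Y reads were 1.19 (1.06 to 1.33) times control in the vehicle and 1.58 (1.43 to 1.76) in the hemin library. These rest on 674 and 832 H3K9me3 reads against 564 and 657 control reads over the whole chromosome. Mapping quality was not given, so wrongly mapped reads cannot be told apart from chromosome Y. Reads on unplaced sequences were 1.045 (1.02 to 1.07) times control in the hemin library but 0.930 (0.910 to 0.949) in the vehicle library. In the control pair, hemin over vehicle was 0.922 (0.823 to 1.03) for chromosome Y and 0.937 (0.919 to 0.956) for unplaced reads.

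Several named genes had enrichments on opposite sides of 1 in the treatments; the differences were not tested, and these genes had been picked for large ratios. Among those higher in hemin, 6 did so, with ratios of enrichments of 3.75 at Olfr1160, 4.95 at Ctag2, 2.64 at Gucy2c, 3.06 at Cldn34d, 2.54 at Speer4f1 and 2.56 at Olfr1209. Among those lower in hemin, 11 did so: the ratio was 0.313 at Krtap14, 0.326 at Vps35, 0.501 at Mageb17-ps, 0.368 at Olfr154, 0.554 at Olfr411 and 0.311 at Olfr457. It was 0.433 at Olfr1286, 0.529 at Vmn1r12, 0.405 at Vmn2r28, 0.393 at Olfr591 and 0.528 at Olfr1443. Of these named genes, only Cldn34d had enrichment intervals that excluded 1 in both libraries. They were 0.306 to 0.955 in the vehicle and 1.07 to 2.65 in the hemin library. At the others the side of 1 was not resolved in at least 1 library. Clustered protocadherins also lay on opposite sides, with a ratio of medians of 0.925; their median log2 hemin over vehicle ratio was −0.03 in the H3K9me3 pair and 0.17 in the control pair. So did chromosome 5 with 1.017 and chromosome 18 with 0.990, likewise untested.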

How the results depend on the processing

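Counting both strands, using whole genes, centring on the median and the share in thinned libraries were chosen after seeing the data. No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out. The mapping quality filter was not run. Across all alternatives, 253 values of the main results were classed as having stayed and 37 as moved. Another 9 came to stand apart from random lists (heme response, protocadherin and housekeeping values). In turn, 3 no longer stood apart (olfactory, Zfp and vomeronasal ratios). Values classed as having stayed did not all keep their sign. The log2 ratio at the Tfrc ends, 0.10 in the main setting, was so classed at −0.06 (± 5 kb) and −0.29 (whole gene). Of the named genes' values, 2150 stayed inside their main interval, 20 moved and 1 reversed. The reversed one was Pcdha4, with a log2 ratio of 0.0396 over the whole gene. The 2-fold mark and the minimums of fragments do not enter the named genes' values, so under those settings none could move. Likewise, the Tfrc gene body ratio could not move with ends ± 1 kb, ± 5 kb or whole genes, yet is counted among the 253. The numbers that stayed thus overstate how much was tested. A sign change was called reversed only where the main interval excluded no difference, so other sign changes can be among the values that stayed. Counts of differing regions depend on depth, with medians of 47 and 49 H3K9me3 fragments per enriched window. Where a cause is not given by the setting itself, the cause was not tested.

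Dividing by the control ratio, which adds the counting noise of the controls, gave 1021 windows higher and 521 lower, and 1073 gene regions higher and 2379 lower, and put the olfactory ratio at −0.0832. A pseudocount of 5 left 89 windows lower and 285 gene regions higher. A 2-fold mark left 22 windows higher and 8 lower, and 30 gene regions higher and 104 lower. With 50 kb windows, 304 were enriched in vehicle, 739 in hemin and 83 in both, the share ratio was 1.099, and 6 were higher and 1 lower. At 1.5-fold over control, 35950, 40993 and 18777 windows were enriched in vehicle, hemin and both, and 1903 were higher and 742 lower. At 3-fold, these were 553, 675 and 39, with 10 higher and 4 lower and a share ratio of 1.08. Gene ends ± 1 kb gave 1228 regions higher and 2841 lower, a Tfrc log2 ratio of −0.55, and medians of −0.0881 for Zfp and −0.0337 for vomeronasal genes. Ends ± 5 kb gave 174 higher and 548 lower, a heme response enrichment of −0.58 and a protocadherin ratio of 0.0337. Centring, which balances the directions by construction, gave 247 windows higher, and 778 gene regions higher and 828 lower. Whole genes gave 242 higher and 707 lower, a heme response enrichment of −0.54, a housekeeping ratio of −0.26 and a protocadherin ratio of 0.0474. Both strands put heme response enrichment at −0.63 and the protocadherin ratio at 0.0544, and keeping duplicates put the heme response ratio at 0.0168 and the protocadherin ratio at 0.0737, all on the log2 scale.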

Other observations

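Among chromosomes 1 to 19 and X, chromosome X stood highest in H3K9me3 over control, at 1.199 (1.194 to 1.204) in the vehicle and 1.22 (1.21 to 1.22) in the hemin library, and chromosomes 11 (0.897 and 0.871) and 19 (0.931 and 0.905) lowest. Enriched windows formed 5008 runs, of which 4294 were single windows. The longest, chosen after its values were seen, was 70 kb on chromosome 7 (87420001 to 87490000, mm10) and overlapped Tyr, which encodes tyrosinase, the enzyme of melanin synthesis. It had an enrichment of 2.57 (2.08 to 3.18) in the vehicle and 2.03 (1.69 to 2.44) in the hemin library, from 315 H3K9me3 fragments in each. A run of 50 kb on chromosome X (130090001 to 130140000) overlapped Diaph2, which encodes an actin-nucleating formin, with 2.13 (1.67 to 2.72) and 2.56 (2.02 to 3.26). It held 215 vehicle and 214 hemin H3K9me3 fragments, while its control pair had a ratio of 0.831 (0.628 to 1.10). The 2 enrichments thus differ through the controls, not through H3K9me3.

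Depth in the control libraries differed between chromosomes in the same way in both. Relative to the median of the autosomes, the median control fragments per window were 1.45 on chromosome 15, 1.25 in vehicle and 1.26 in hemin on chromosome 11, 0.679 and 0.682 on chromosome 14, and 0.547 and 0.545 on chromosome X. Chromosome Y held 0.00401% of the vehicle control reads and 0.00362% of the hemin control reads. Enrichment divides H3K9me3 by control fragments of the same region, so these differences in depth cancel in its expected value but not in its counting noise. Enriched windows were most frequent on chromosomes X (7.39%) and 14 (3.46%), where control depth was lowest, against 0.468% on chromosome 11. Chromosome 9, also below the autosome median in depth, had 0.892%. The part of depth in these calls was not tested. Hemin over vehicle ratios were not divided by control in the main results.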
